A study of Mus musculus with 2 samples.

How the data were processed

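Coronal brain sections of 2 C57BL/6J mice at postnatal day 5 were profiled by MERFISH, an imaging method that reads RNA molecules in place by their barcodes, on the Vizgen MERSCOPE platform. The labels give 1 section at level 125 and 1 section at level 133 of the Paxinos atlas, cut at 10 micrometres, from different animals. The panel holds 478 genes and 72 blank barcodes that stand for no gene.

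Per the file headers, the deposited tables give transcript counts per segmented cell and barcode, with no normalization. The authors also give a position, a volume and the summed image intensity of 5 stains per segmented cell, as image brightness not divided by volume. A further deposited table gives the position and image plane of every decoded transcript and the cell it was assigned to. The decoding and segmentation software, its version and its filters are not given in the sources used here. The counts were checked to be whole numbers that add up to each cell's stated total.

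Cells were kept with 20 or more panel transcripts and with a volume of at least 50 cubic micrometres and at most 3 times the section's median. This kept 132783 cells at level 125 and 108361 cells at level 133. Counts were scaled to each cell's total and log transformed, and 40 principal components and 15 neighbours per cell gave a graph that was clustered by Leiden at resolution 1, both sections together. The tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.

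The marker genes of each cell class, the gene lists, the tests, the thresholds and the first set of alternatives were fixed before the data were examined. The rule that turns markers into cluster names was set after the clusters had been seen. A cluster took the name of the class with the most markers among its 10 most raised genes, given at least 3 markers there (2 for classes with up to 4 panel markers) and at least 3 markers raised 1.5-fold with a mean count of 0.1 or more. An interneuron name also needed Lhx6 or Adarb2 raised 3-fold. This last condition kept out clusters 8, 16 and 18, which together held 22.8% of all Sst-positive cells at level 125 and 27.7% at level 133. Names end in "-like" because they rest on panel markers alone. No doublet caller was run, and segments that merge neighbouring cells remain possible.

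Sst-positive cells held at least 5 Sst transcripts and Sst-negative cells at most 1. The neighbourhood of a cell was the most frequent named neuronal class, other than interneuron, among its 50 nearest cells. After the clusters were seen, a second version let unnamed clusters compete if their summed level of Syp, Syt4 and Nefl reached 35000 on a scale of counts relative to the total (CPM), and pooled clusters 2 and 10.

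Cells are not replicates, so counts were summed per section and class. Sst-positive and Sst-negative interneuron-like cells were compared with edgeR (TMM scaling, filterByExpr, quasi-likelihood F test, 2-sided) on 4 sums with the section as a block, which leaves 1 residual degree of freedom. Benjamini-Hochberg adjustment covered the 477 panel genes other than Sst, at a threshold of 0.05. The filter removed 0 genes. The SE is the absolute log2 fold change divided by the root of F. It rests on a variance moderated over all genes, with a median prior degree of freedom of 6.24, and does not measure the spread between the 2 sections. The common biological coefficient of variation was 0.102. Tested on simulated data with the same means and dispersions, the test recovered 46 of 66 genes changed 1.5-fold, 67 of 67 changed 2-fold and 67 of 67 changed 4-fold, called 2 of 277 unchanged genes, and called 0 genes when none was changed. The simulated counts were drawn from this fit's own dispersions. They show how the test runs under its own model and do not measure false calls in these data.

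The comparison of upper-layer with deep-layer neighbourhoods was not run, because no cluster took the upper-layer name. The comparison of cortical with striatal neighbourhoods was to be tested only with at least 50 cells in each sum. The striatal sum at level 125 held 43 cells, so it is given as values per section, and the test was run only in the planned setting of 100 nearest cells, where each sum reached 50. Levels were compared as values with no test, since each level has 1 section. Shares carry exact Clopper-Pearson binomial intervals and counts carry exact Poisson intervals, at 95%, and a share of 0 carries a limit of 3 cells. All of these cover counting error only.

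Named genes followed a rule set before the data were examined. For Sst-positive against Sst-negative cells these are the 15 largest rises and 15 largest falls past the threshold, the same way in both sections, with at least 100 counts in the higher class of each section. For neighbourhoods they are the 8 largest each way, ranked for want of a test by the smaller of the 2 sections' log2 ratios, with a mean count per Sst-positive cell at least that of the other cells there. For levels they are up to 5 each way per class at 2-fold or more with at least 200 counts. Up to 4 members of each of the gene lists were added, with Sst, Lhx6, Gad1 and Gad2. Values of 1 gene are not reported here, although it stayed in the tests and counts. The lists covered MGE lineage regulators, CGE lineage genes, Sst subtype markers, neuropeptides and neuropeptide receptors, glutamate receptors, GABA synthesis and receptors, voltage-gated ion channels, activity-regulated genes, cell adhesion and synapse organisers, axon guidance, cell death and survival, and monoamine and acetylcholine receptors.

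Alternatives changed 1 choice at a time, except that thinning also left out cells with under 100 transcripts, 1328 of 10038 interneuron-like cells at level 125 and 1596 of 7975 at level 133. They covered the Sst limits, the minimum transcripts per cell, the scaling, DESeq2 in place of edgeR, no block, each section alone, a recount within 5 micrometres of the cell centre, Sst-negative cells over 20 micrometres from any Sst-positive cell, cortical neighbourhoods only, 25 or 100 nearest cells, Leiden resolutions of 0.5 and 2, clustering of each section alone, thinning of each cell to 100 transcripts, marker minimums of 1 and 5 transcripts, and counts per volume. Alternatives added after the data were seen were each interneuron-like cluster alone, these clusters as blocks, the addition of clusters 8, 16 and 18, the competing unnamed clusters, the thinned fit of Sst-positive against Sst-negative cells, and deep-layer neighbourhoods alone for the level comparison.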

Results

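The data describe where Sst-positive interneurons, a class of inhibitory neuron that releases the peptide somatostatin, lie in the brain of the young mouse and which panel genes they hold. There was 1 section per atlas level, so the 2 levels have no replicates. Level 125 gave 139637 segmented cells with 35539992 gene transcripts, and level 133 gave 118952 cells with 20170648 gene transcripts. Kept cells held a median of 216 transcripts at level 125 and 156 at level 133. The mean blank barcode reached 5.18% of the mean gene barcode at level 125 and 5.34% at level 133. At level 125, 136 panel genes lay at or under the highest blank barcode, and at level 133, 178 did. The fields of view are numbered from 945 to 2016 at level 125 and from 0 to 943 at level 133. Level, animal and imaging cannot be told apart.

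GABAergic interneuron-like cells made up 7.56% (95% interval 7.42 to 7.70) of kept cells at level 125 and 7.36% (7.20 to 7.52) at level 133. Striatal projection neuron-like cells, marked by Penk, Meis2, Sp9, Rarb and Pdyn, were 3.73% at level 125 and 11.1% at level 133. Deep-layer cortical glutamatergic neuron-like cells held 4.69% and 5.44%, astrocyte-like cells 10.1% and 7.56%, and thalamic neuron-like cells 3.47% and 2.05%, level 125 first. Immature or migrating neuron-like cells held 4.65% and 3.93%, and Cajal-Retzius cell-like cells 0.287% and 0.111%. Of the 38 clusters, 26 took no name, and these held 65.5% of cells at level 125 and 62.5% at level 133. No test was run on these shares.

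Sst-positive cells were 11.5% of interneuron-like cells at level 125 (1152 of 10038, interval 10.9 to 12.1) and 9.94% at level 133 (793 of 7975, interval 9.30 to 10.6). They lay in the 3 interneuron-like clusters. Cluster 12, raised for Maf, Lhx6 and Elfn1, held 410 of them at level 125 and 342 at level 133. Cluster 11, raised for Adarb2, Crhbp and Lhx6, held 593 and 250. The small cluster 33, raised for Npy, Nos1 and Nkx2-1, held 149 and 201. Depth bears on these shares. Among the interneuron-like cells with at least 100 transcripts 12.96% were Sst-positive at level 125 and 12.1% at level 133, and with these cells thinned to 100 transcripts the shares were 4.13% and 4.48%. Only 48.8% of all Sst-positive cells at level 125 and 53.0% at level 133 were interneuron-like.

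**Figure D1:**
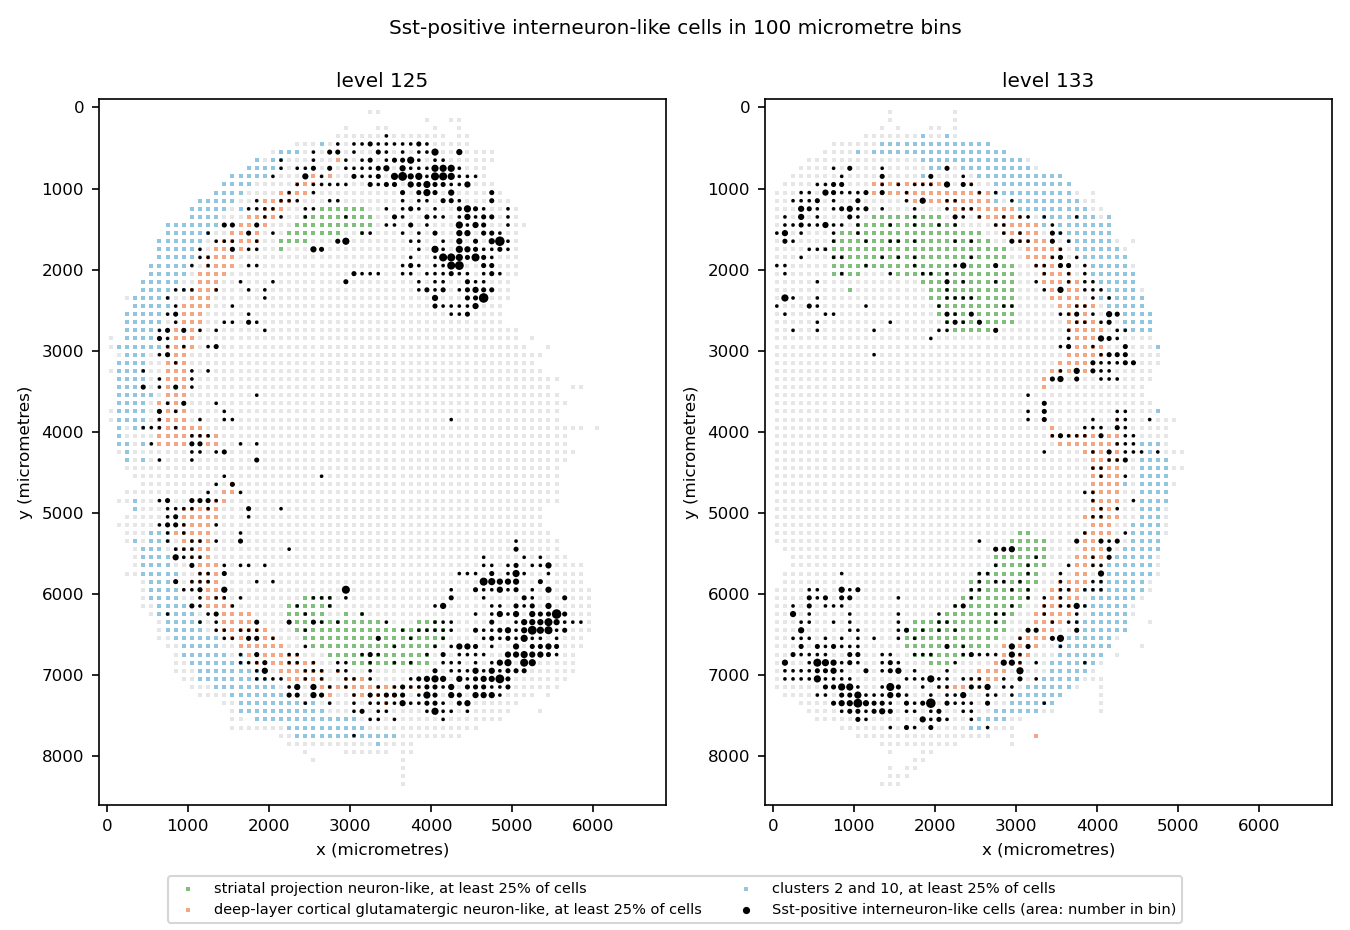
Each square is a 100 micrometre bin of the section (axes in micrometres), coloured where at least 25% of its cells belong to the named group, and black dots give the Sst-positive interneuron-like cells in the bin by area. The band of clusters 2 and 10 lies outside the deep-layer band and holds few black dots in both sections.

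Sst-positive interneurons were scarce around clusters 2 and 10, unnamed neuronal clusters raised for Mef2c and for Satb1 or Pou3f2 that lay near the tissue edge. Among interneuron-like cells in the neighbourhoods of clusters 2 and 10, 1.49% were Sst-positive at level 125 (29 of 1947, interval 0.9997 to 2.13) and 0.916% at level 133 (20 of 2184, interval 0.560 to 1.41). In deep-layer neighbourhoods of the same kind the shares were 13.5% (137 of 1014, interval 11.5 to 15.8) and 14.5% (134 of 927, interval 12.3 to 16.9). The deep-layer share was 9.07 times the share around clusters 2 and 10 at level 125 (interval 6.04 to 14.1) and 15.8 times at level 133 (9.82 to 26.7). Cells of cluster 10 lay a median of 177 and 135 micrometres from the tissue edge, those of cluster 2 lay 293 and 285 micrometres from it, and those of the deep-layer cluster 7 lay 725 and 762 micrometres from it, level 125 first. Nearness to the edge alone did not go with a low share, since cells of the unnamed cluster 15 lay 202 and 160 micrometres from it, and around them 167 of 812 and 70 of 389 interneuron-like cells were Sst-positive. This comparison was added after the clusters were seen.

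With named classes alone, deep-layer neighbourhoods held 330 Sst-positive of 2930 interneuron-like cells at level 125 (11.3%) and 320 of 2684 at level 133 (11.9%). Striatal neighbourhoods held 43 of 318 (13.5%) and 114 of 777 (14.7%). At level 125 most of the 1152 Sst-positive interneuron-like cells lay in other neighbourhoods, as did part of the 793 at level 133. Where unnamed clusters compete, cluster 33 made up 242 of the 269 interneuron-like cells of striatal neighbourhoods at level 125 and 571 of 641 at level 133 (89.1%), against 4.14% and 3.34% in deep-layer neighbourhoods. In deep-layer neighbourhoods cluster 12 made up 74.0% and 77.8%. Cluster 11, with 593 and 250 Sst-positive cells in all, had only 2 and 1 of them there.

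**Figure D2:**
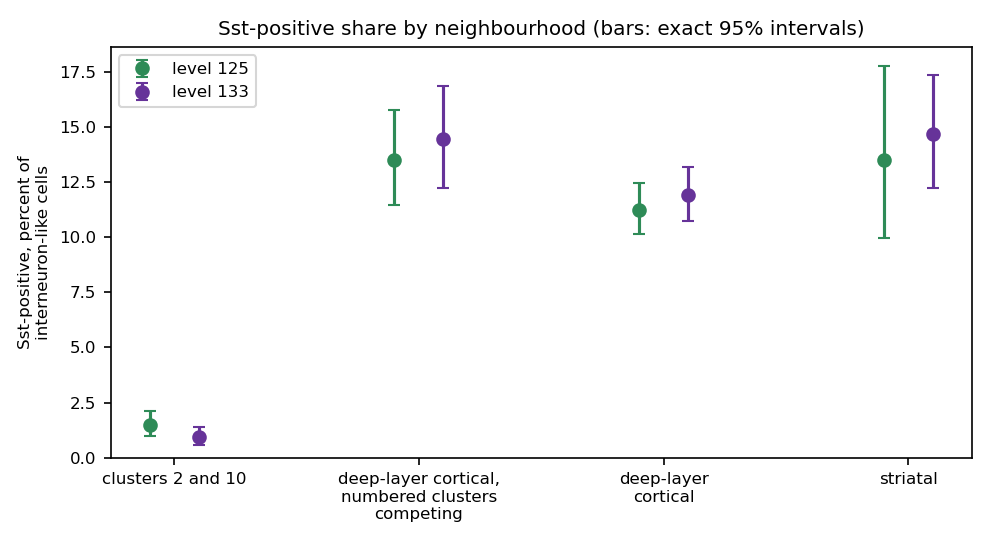
Points give the share of interneuron-like cells that were Sst-positive in each kind of neighbourhood (vertical axis, percent), by section, with exact 95% intervals. The shares of 1.49% and 0.916% around clusters 2 and 10 lie below those of the other neighbourhoods shown.

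Sst-positive interneuron-like cells differed from Sst-negative ones in 271 of the 477 genes tested by edgeR, 130 higher and 141 lower, over 2 sections. The largest rise was in Npy, which encodes neuropeptide Y, at 26.7-fold (log2 4.74 ± 0.17 SE, adjusted p 2.63e-06). Nos1, the neuronal nitric oxide synthase, was 7.32-fold higher (log2 2.87 ± 0.26) and Crhbp, which binds corticotropin-releasing hormone, 5.99-fold higher (log2 2.58 ± 0.16). Chodl rose 4.03-fold, the synapse organiser Elfn1 3.27-fold, the nicotinic receptor subunit gene Chrna2 3.03-fold and the substance P receptor gene Tacr1 3.02-fold. Adarb2, a marker of interneurons from the caudal ganglionic eminence, was 10.1-fold lower (log2 -3.33 ± 0.14, adjusted p 4.81e-06).

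The other large rises were in Tent5a, Prkcq, Mrap2, Emilin2, Lgals1, Ppp3r2, Rbp4 and Dach1, between 3.98-fold for Tent5a and 2.80-fold for Dach1. The other large falls were in the chemokine gene Cxcl14 (5.85-fold), Igsf11 (5.30-fold), the GABA receptor subunit gene Gabrd (4.68-fold), Cck (3.24-fold), Id2 (3.14-fold), Nfix (3.10-fold), Kit (log2 -1.59), the neuregulin receptor gene Erbb4 (2.90-fold) and Mef2c (2.84-fold), and, down to 2.61-fold for Pdzrn3, in Kcnip2, Hapln1, Nfib, Adamts17 and Pdzrn3. Gad2, which encodes an enzyme that makes GABA, was 1.47-fold higher, and Gad1 did not pass (log2 0.07 ± 0.05, adjusted p 0.27). All 271 genes differed the same way in both sections, although the size rested on the section for Nos1 (log2 2.27 at level 125 and 3.49 at level 133) and Chodl (1.45 and 2.71). The SE borrows its variance in part from all genes, so it is not the spread between the 2 sections.

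**Figure D3:**
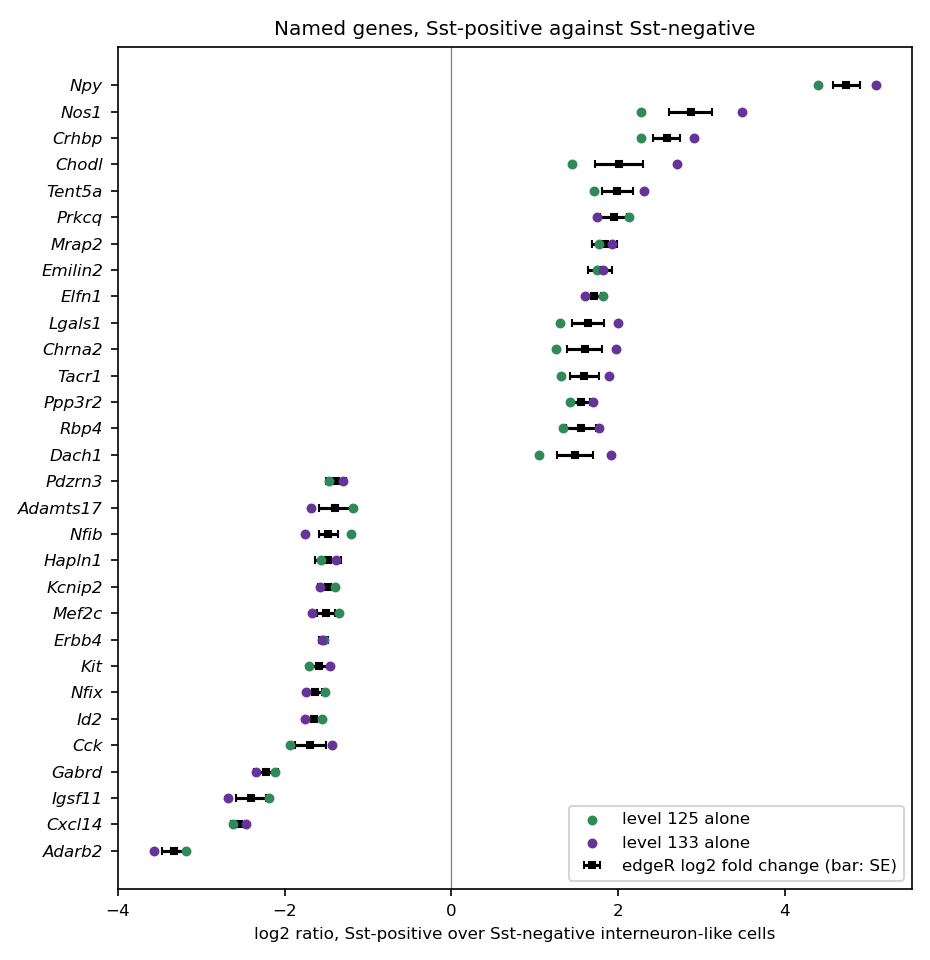
Squares give the edgeR log2 fold change of Sst-positive over Sst-negative interneuron-like cells with its SE, and coloured points give each section alone. Each of the 30 genes shown lies on the same side of 0 in both sections, from 4.74 for Npy to -3.33 for Adarb2.

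Lineage genes went both ways. Of 12 measured MGE lineage regulators, from the medial ganglionic eminence where Sst interneurons arise, 3 rose (Lhx6, 1.74-fold; Sox6; Satb1), 5 fell (among them Mef2c, Zeb2, 2.09-fold, and Nkx2-1, 1.63-fold) and 4 did not pass, with 8 past the threshold adjusted over the list alone. Of 7 CGE lineage genes, Adarb2, Cck, Id2 and Nr2f1 fell, Npas1 rose and 2 did not pass, with 5 adjusted over the list alone. Of 27 Sst subtype markers 11 rose, such as Npy, Nos1 and Chodl, 7 fell, such as Nfix, and 9 did not pass, with 18 adjusted over the list alone.

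Among 17 tested neuropeptides and receptors, 8 rose (Npy, Crhbp, Tacr1 and Cort among them), 4 fell (among them Cck) and 5 did not pass, with 12 adjusted over the list alone. None of the 4 glutamate receptor genes passed in edgeR or DESeq2, and 0 did adjusted over the list alone. Grik4 alone had an unadjusted edgeR p under 0.05 (log2 0.48, p 0.0303, adjusted p 0.0531), and Grm8 had log2 0.25, Grin2a 0.12 and Grm5 -0.14. Of 9 GABA genes, 3 rose (Gad2, Gabra2, Gabrb1), 4 fell (Gabrd, Gabrg3, Gabra4, Gabbr2) and 2 did not pass, with 7 adjusted over the list alone. The calcium channel subunit gene Cacna2d3 (2.79-fold) and the potassium channel gene Kcnc4 (1.88-fold) rose among 3 voltage-gated channel genes and Kcnip4 did not pass (log2 -0.19), with 2 adjusted over the list alone. Of 4 activity-regulated genes, Fosl2 (1.63-fold) and Nr4a2 (1.42-fold) rose, and Egr2 and Igf1 did not pass, with 2 adjusted over the list alone.

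Adhesion genes had 6 of 23 higher, such as Elfn1, Ptpru (2.65-fold) and Cbln4 (2.16-fold), 5 lower, such as Clstn2 (2.23-fold), and 12 that did not pass, with 11 adjusted over the list alone. Axon guidance genes had 2 of 12 higher (Ntn1, 2.18-fold, and Sema3e) and 6 lower (among them Cxcl14, Erbb4 and Epha4, 2.21-fold), and 4 did not pass, with 8 adjusted over the list alone. The 1 measured survival gene, the neurotrophin receptor gene Ntrk3, fell 1.38-fold, also adjusted over the list alone, where 1 passed. Among 9 monoamine and acetylcholine receptor genes, 5 rose (Chrna2, Chrm2, 1.75-fold, Htr1d, 1.78-fold, Htr1a and Adra2a), Adra1b fell 1.63-fold and 3 did not pass, with 6 adjusted over the list alone.

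Many of these list members were not called with the clusters and sections as blocks. Of the MGE lineage regulators called, 4 of 8 remained (Lhx6, Satb1, Zeb2 and Mef2c), of the CGE lineage genes 1 of 5 (Id2), of the Sst subtype markers 7 of 18 and of the neuropeptides and receptors 7 of 12. Of the GABA genes 2 of 7 remained (Gabrg3 and Gabrd), of the adhesion genes 4 of 11 and of the axon guidance genes 3 of 8. Both voltage-gated channel genes remained, and Chrna2 was the 1 of 6 monoamine and acetylcholine receptor genes that did. Fosl2 and Nr4a2, the activity-regulated genes, and Ntrk3 were no longer called, with log2 0.59, 0.91 and -0.36 in that fit. The coefficient of variation was 0.360 there against 0.102, and of the 45 list genes no longer called 39 kept at least 50% of their log2 fold change, such as Chodl (2.03), Chrm2 (0.94) and Gabra4 (-0.55). Nos1 (1.42), Ntn1 (0.49), Nr2f1 (-0.27) and Adra1b (-0.19) did not, and Npas1 (-0.39) and Slitrk1 (0.07) turned in sign.

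Several of these differences were not shared by the 3 interneuron-like clusters. Nos1 had log2 5.02 in cluster 33 alone, 0.29 in cluster 11 and -0.08 in cluster 12, and Chodl had 5.33, 1.25 and -0.05 in the same order. Npy had 6.07, 4.01 and 2.08, Crhbp 3.83, 2.46 and 2.57, and Adarb2 -0.86, -3.73 and -0.47. Cxcl14 had -3.91 in cluster 11, -1.38 in cluster 33 and 0.37 in cluster 12. The direction also turned for Fosl2, Nr4a2 and Ntn1 in cluster 11 alone, for Tacr1, Htr1d and Nkx2-1 in cluster 12 alone, and for Gad2, Adra1b, Nr2f1 and Pdzrn3 in cluster 33 alone. Of the genes that did not pass over all clusters, Grin2a had 2.06 in cluster 33 and -0.22 in cluster 12, Grm8 had -2.73 and 0.87, and Igf1 had 1.07 and 1.27 but -1.34 in cluster 11. Differences between clusters were not tested. With the clusters and sections as blocks, edgeR called 82 genes, all among the 271. Adra1b, lower over all clusters, was higher in cluster 33 alone at log2 1.14. Of the 30 most changed named genes, 29 kept at least 50% of their log2 fold change, Nos1 being the exception, and 21 stayed past the threshold. Without a block for the section, 128 genes were called. Among 72 blank barcodes, 9 were at least 2-fold higher in Sst-positive cells in both sections. The highest was 2.88-fold higher in its lower section and 4.90-fold at level 133. Of the 130 higher genes, 116 had an edgeR fold change over both sections at or under 2.88-fold. By their lower section, level 125, others also lay under it, such as Chodl (log2 1.45), Tacr1 (log2 1.31) and Chrna2 (log2 1.26).

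Subtype markers were counted at 3 or more transcripts per cell. Among the 27 measured, Npy was the most frequent, in 461 of 1152 Sst-positive cells at level 125 (interval 37.2% to 42.9%) and 41.6% at level 133 (interval 38.2% to 45.1%), against 1.28% and 1.05% of Sst-negative interneuron-like cells and 0.475% and 0.317% of astrocyte-like cells. Nos1 was in 14.1% and 21.9%, against 2.81% and 1.30% of Sst-negative cells. Calb1, which encodes calbindin, was in 17.6% at level 125 and 5.93% at level 133, against 7.64% and 1.96%. Cdh13 was in 30.6% and 25.7% against 16.5% and 11.6%, Pdyn in 6.16% and 7.31% against 3.34% and 2.71%, Cbln4 in 6.94% and 5.04%, Chodl in 3.39% and 1.89% and Chrna2 in 0.868% and 2.02%, level 125 first. The highest share of any blank barcode in Sst-positive cells was 4.25% at level 125 and 1.39% at level 133. Chodl and Chrna2 lay under it at level 125 and not far above it at level 133.

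Nfix and Rxfp1 ran the other way. Nfix was in 23.5% and 19.4% of Sst-positive cells against 42.7% and 40.5% of Sst-negative cells, and Rxfp1 in 5.99% and 5.17% against 10.7% and 9.34%. Etv1 and Nts were in 0 of 1152 cells at level 125, which allows up to 0.260%, and in 0 of 793 at level 133, which allows up to 0.378%. Calb2 was in 8.16% and 3.03% of Sst-positive cells but also in 4.88% and 3.49% of astrocyte-like cells. With cells thinned to 100 transcripts Calb2 was in 0.531% and 0.259% of Sst-positive and 1.78% and 3.08% of astrocyte-like cells. The astrocyte-like class is an imperfect background, since its cluster 9 held Syp, Syt4 and Nefl at 36788 CPM together, near the 37853 of cluster 33. Median depth was 385.5 transcripts in Sst-positive cells, 222 in Sst-negative cells and 148 in astrocyte-like cells at level 125, and 306, 176 and 90 at level 133. Thinned to 100 transcripts, Npy was in 18.2% and 31.9% of Sst-positive cells and Nos1 in 10.3% and 18.1%. Thinned in the same way, Calb1 was in 1.68% and 1.17% of Sst-positive and 1.71% and 0.926% of Sst-negative cells, Cdh13 in 3.45% and 2.72% against 2.30% and 2.86%, and Pdyn in 0.974% and 2.33% against 1.27% and 1.26%, so no difference in the same direction in both sections was detectable at this depth.

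**Figure D4:**
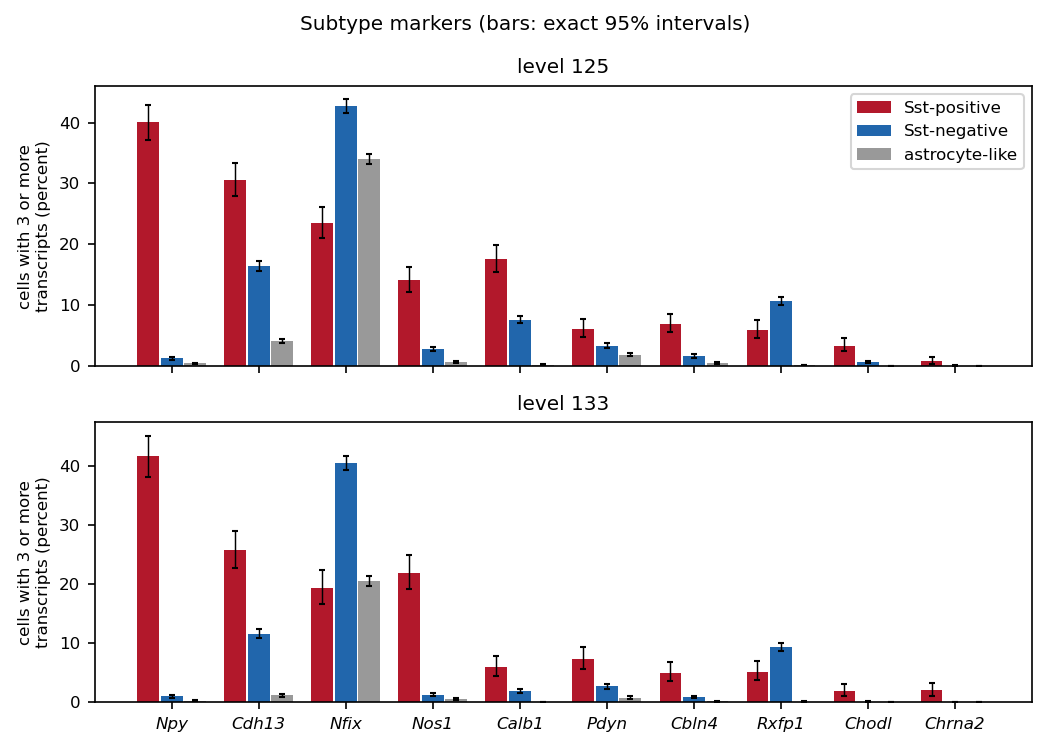
Bars give the share of cells with 3 or more transcripts of each marker (vertical axis, percent) in Sst-positive and Sst-negative interneuron-like cells and in astrocyte-like cells, with exact 95% intervals. Npy is in 461 of 1152 and 330 of 793 Sst-positive cells, and Nfix and Rxfp1 are lower there than in Sst-negative cells.

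Sst-positive cells in striatal neighbourhoods held far more Npy, Nos1 and Epha4 than those in deep-layer cortical neighbourhoods. After TMM scaling Epha4, a receptor for ephrins, was 10.9-fold higher in striatal neighbourhoods at level 125 (interval 8.70 to 13.6) and 9.49-fold at level 133 (7.91 to 11.4). Part of this may come from neighbouring cells. In striatal neighbourhoods its mean count was 3.4 per Sst-positive and 2.9 per other cell at level 125, and 2.9 and 2.6 at level 133. Npy was 9.05-fold and 8.42-fold higher there, and Nos1 6.43-fold and 7.64-fold. Sst itself was 2.57-fold and 2.87-fold higher, Sox2 2.67-fold and 2.94-fold, B3gat1 2.33-fold and 2.89-fold, Ptprt 1.97-fold and 2.57-fold, and Aff2 2.12-fold and 1.94-fold. These ratios are relative to each sum's total. Per cell the mean Sst count was 15.6 in striatal against 10.6 in cortical neighbourhoods at level 125, and 15.4 against 10.3 at level 133. For Aff2 at level 133 it was 1.87 against 1.85. The choice of cells with at least 5 Sst transcripts also limits the Sst ratio. The neighbourhoods differ in their clusters, since cluster 33, raised for Npy and Nos1, made up most interneuron-like cells of striatal neighbourhoods and cluster 12 most of those of deep-layer neighbourhoods. The ratios were not separated by cluster.

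Deep-layer cortical neighbourhoods held more Npas1, a transcription factor gene, by 15.97-fold at level 125 (interval 6.21 to 58.7) and 26.7-fold at level 133 (interval 12.9 to 66.7). Satb1, a chromatin organiser needed by Sst interneurons, was 11.2-fold and 10.8-fold higher there (6.05 to 23.3 and 6.51 to 19.4), and Lypd6 10.96-fold and 16.9-fold. Klhl14, Egln3, Bcl6, Igf1 and Tmem132c were also higher in both sections. Each of these 8 genes had 16 or fewer counts in either striatal sum, so that their ratios are loose: Klhl14, with 1 striatal count, was 10.4-fold higher at level 125 with an interval of 1.83 to 413. Gad2 was 1.74-fold and 1.76-fold higher and Gad1 1.36-fold and 1.43-fold, while Lhx6 was 1.46-fold and 1.75-fold higher in striatal neighbourhoods. Per Sst-positive cell the mean Lhx6 count was instead lower in striatal neighbourhoods, at 5.26 against 6.27 at level 125 and 4.98 against 5.47 at level 133.

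These values rest on 330 and 320 cortical and on 43 and 114 striatal Sst-positive cells. Their neighbourhoods go by named classes alone, although most cells are in unnamed clusters. Where unnamed clusters competed, 137 and 134 cortical and 37 and 102 striatal cells kept the name, so most of the cortical ones lost it. Of 161 genes with enough counts, 55 were at least 2-fold higher in cortical and 9 in striatal neighbourhoods in both sections. Of these, 47 of the 55 and 6 of the 9 were at least as abundant per Sst-positive cell as in the other cells there. The others may come from neighbouring cells, and so may part of the Epha4 counts, which passed this limit only narrowly. The minimum count applies to the higher group, and the striatal sums hold fewer cells, so that fewer genes high in striatal neighbourhoods can reach it and 55 and 9 cannot be compared with each other. Without TMM scaling the median gene shifted toward cortical neighbourhoods by 0.27 at level 125 and 0.32 at level 133 on the log2 scale. With 100 nearest cells, edgeR called 129 of 460 genes higher in cortical and 109 higher in striatal neighbourhoods. Of these, 101 of the 129 and 72 of the 109 were at least as abundant per Sst-positive cell as in the other cells there. The prior degree of freedom was infinite, so that the spread was pooled over all genes. All 16 named genes were among the calls, but they had been picked by size from nearly the same cells, so this is no separate support. The neighbourhoods of clusters 2 and 10 held only 29 and 20 Sst-positive cells and stand in for no upper-layer comparison.

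**Figure D5:**
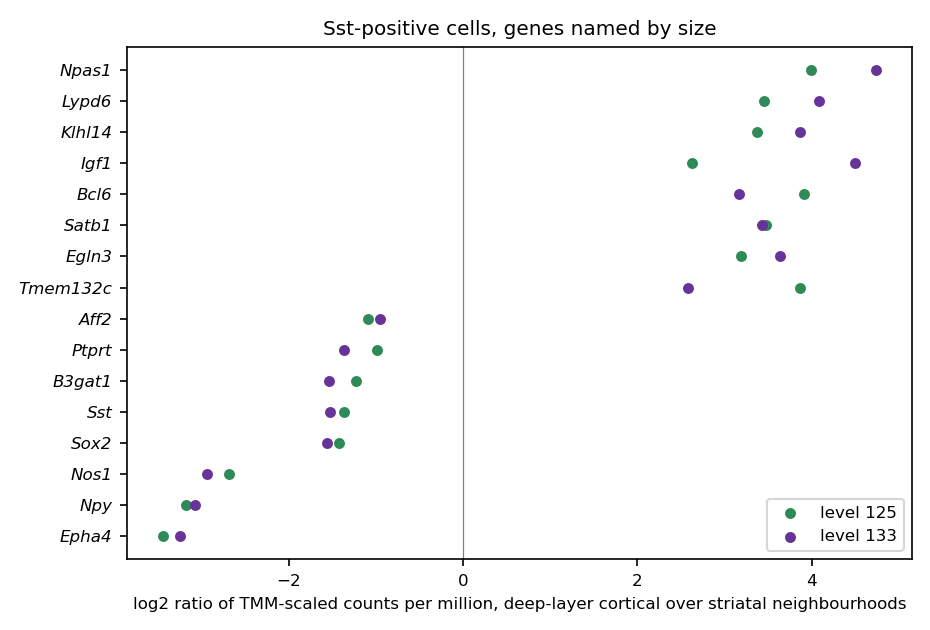
Points give the log2 ratio of TMM-scaled CPM in Sst-positive cells of deep-layer cortical over striatal neighbourhoods for the 16 genes named by size, by section. Epha4, at -3.44 and -3.25, Npy, at -3.18 and -3.07, and Nos1, at -2.68 and -2.93, lie farthest to the striatal side.

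Between levels, among genes with at least 200 counts in the higher section, Sst-positive cells of all neighbourhoods differed most in the guidance genes Ntn1 and Nrp2. Ntn1, the netrin gene, was 2.45-fold higher at level 133, with 1941 CPM (interval 1774 to 2120) against 793 (715 to 878). Penk, which encodes enkephalin precursor, was 2.32-fold and Dach1 2.11-fold higher at level 133, and Pou3f2 had 1664 CPM there against 831. Nrp2, a semaphorin receptor gene, was 2.52-fold higher at level 125, with 1901 CPM (1778 to 2029) against 754 (651 to 868), and Dgkb was 2.11-fold higher. Sst itself differed by 1.10-fold and Lhx6 by 1.09-fold. The Sst ratio is limited by the choice of cells with at least 5 Sst transcripts, so it does not show that Sst was stable. These ratios mix clusters, as cluster 11 held 593 of 1152 Sst-positive cells at level 125 and 250 of 793 at level 133, and cluster 33 held 149 and 201, and they were not separated by cluster. In deep-layer neighbourhoods alone the log2 ratio of level 133 over level 125 was 0.33 for Ntn1, against 1.29 over all neighbourhoods, -0.56 for Nrp2 (-1.33), 0.16 for Dach1 (1.08), 0.84 for Penk (1.22), 0.65 for Pou3f2 and -1.17 for Dgkb (-1.07).

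Other cell classes also had differences by size, some of them shared between classes. In Sst-negative interneuron-like cells Th was 3.06-fold higher at level 133, and Nrp2 was 2.76-fold, Chodl 2.69-fold and Calb1 2.10-fold higher at level 125. Striatal projection neuron-like cells held 2.36-fold more Cxcl14 at level 133 and 3.39-fold more Cpne4 at level 125. Thalamic neuron-like cells held 4.84-fold more Tshz2 and 4.12-fold more Vat1l at level 133, and 7.90-fold more Cck at level 125. In immature or migrating neuron-like cells Penk was 2.49-fold higher at level 133 and Sema5a 3.19-fold higher at level 125. In astrocyte-like cells Cck was 3.19-fold higher at level 125, the same way as in thalamic neuron-like cells. The astrocyte-like cluster 9 held Syp, Syt4 and Nefl at 36788 CPM together, and neuronal transcripts in the astrocyte-like class were not separated out. The median absolute log2 ratio was 0.28 over 321 genes in Sst-positive cells, 0.20 in deep-layer cells and 0.46 in thalamic cells. With counts per cubic micrometre it was 0.55 in Sst-positive cells. The Sst-negative interneuron-like and the immature or migrating neuron-like classes pool clusters in other shares at each level. Cluster 33 held 317 of 8021 Sst-negative interneuron-like cells at level 125 and 814 of 6593 at level 133, cluster 11 held 4500 and 2743, and the immature or migrating neuron-like cells were 4345 of cluster 13 and 1826 of cluster 22 at level 125 and 2576 and 1686 at level 133. These ratios were not separated by cluster. With 1 section per level no test was run.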

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

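The share around clusters 2 and 10, the fit with clusters as blocks and the rule for genes that went opposite ways were chosen only after the results had been seen, the last after a 2-fold limit and a smaller one, which left Bmp3 alone, had been tried.

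Some genes went opposite ways in the 2 sections for Sst-positive against Sst-negative cells, and this difference between sections was not tested. Of 477 genes 66 did so at any size, 0 with both sections at 2-fold or more, and 12 with both exact counting intervals away from 0. Of those reported here, the log2 ratios at level 125 and then level 133 were 0.21 and -1.06 for Gpr83, 0.21 and -0.51 for Hopx, 0.34 and -0.27 for Vwc2, 0.16 and -0.28 for Calb2, 0.18 and -0.23 for Fstl1, 0.10 and -0.26 for Nefl, and 0.10 and -0.24 for Pcdh19. They were -0.30 and 0.60 for Bmp3, -0.29 and 0.73 for Egr2, -0.29 and 0.30 for Hs6st2, and -0.21 and 0.07 for Spock1.

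Data that the comparisons do not use also held signal. Of 72 blank barcodes, 9 were at least 2-fold higher in Sst-positive than in Sst-negative cells in both sections. Outside every segmented cell lay 17.5% of gene transcripts at level 125 and 17.5% at level 133. The DAPI brightness per volume of Sst-positive cells was 0.802 times that of Sst-negative cells at level 125 and 0.838 times at level 133.

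The share of Sst-positive cells was lower around clusters 2 and 10 than in deep-layer neighbourhoods. Against fewer transcripts per cell as the cause, thinning to 100 transcripts left a ratio of 12.3 at level 125 (interval 3.71 to 64.4, with 3 cells around clusters 2 and 10) and of at least 20.6 at level 133, where 0 of 1628 cells there were positive. Against another mix of interneuron-like clusters, the ratio within cluster 12 was 7.03 at level 125 and 11.5 at level 133, while cluster 11 held too few positive cells to tell. A true sparseness around these clusters may be the reason, as a hypothesis only, and it would not extend to all cells near the tissue edge, as cluster 15 shows. Segmentation differences were not tested.

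The named genes of Sst-positive against Sst-negative cells were set against depth, cell edges and cluster mix. Thinned to 100 transcripts, 100% of the 30 genes kept at least 50% of their log2 fold change, and 190 of the 271 genes were called again. Because the sums are scaled to their totals, thinning mainly reweights cells, so this outcome was close to fixed beforehand. The Sst classes were also still those set at full depth, so thinning cannot decide on depth as the cause. The recount within 5 micrometres of the cell centre measured distance in x and y only, with the Sst classes still set from whole cells. It therefore cannot exclude transcripts of cells that overlap in depth. In this recount 100% of the 30 genes kept at least 50% of their log2 fold change, and 229 of the 271 were called again. With clusters and sections as blocks 96.7% kept it, but in clusters 11 and 12 alone 24 and 20 of the 30 did and in cluster 33 alone 21 of the 27 tested, so that the part played by the mix of clusters cannot be told apart for the named genes as a set. With these blocks 21 stayed past the threshold, and the coefficient of variation went from 0.102 to 0.360. The blocks take out each cluster's own level in each section. The spread that remains is how the Sst-positive difference varied over clusters and sections. This fit had 12 sums and 5 residual degrees of freedom, so clusters of the same 2 animals acted as replicates. Nos1 went from 2.87 ± 0.26 to 1.42 ± 0.93, Adarb2 from -3.33 ± 0.14 to -1.75 ± 0.64, Cxcl14 from -2.55 ± 0.10 to -1.59 ± 0.72, Chodl from 2.01 ± 0.28 to 2.03 ± 0.86, Nfix from -1.63 ± 0.08 to -1.49 ± 0.44, Tacr1 from 1.59 ± 0.17 to 1.31 ± 0.60, Emilin2 from 1.78 ± 0.15 to 1.31 ± 0.40, Cck from -1.70 ± 0.19 to -1.33 ± 0.46 and Pdzrn3 from -1.39 ± 0.12 to -0.93 ± 0.33, and these were the genes no longer past the threshold.

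The 6 genes named by size between levels in Sst-positive cells were set against a shared detection difference and against regions. A shared difference would move other cells alike, yet 16.7% of the genes went the same way at 1.5-fold or more in both astrocyte-like and striatal projection neuron-like cells, that gene being Dgkb. A smaller shared difference stays open for others too. Pou3f2 was higher at level 133 in every class compared between levels, by 1.28-fold to 2.71-fold, and Penk in all of these but deep-layer cells. Dgkb turned in immature or migrating neuron-like cells (1.09-fold). Cajal-Retzius cell-like cells and unnamed clusters were not among the classes compared. In deep-layer neighbourhoods alone 50% kept at least 50% of their log2 ratio (Dgkb, Penk and Pou3f2), so that another mix of regions cannot be told apart from a difference within regions for the other genes. The mix of clusters, the level and the animal stay open, as they were not tested.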

How the results depend on the processing

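The fits of each cluster alone, with clusters as blocks and with clusters 8, 16 and 18, the thinned fit of Sst-positive against Sst-negative cells, the unnamed competing clusters, all values for clusters 2 and 10, and deep-layer neighbourhoods alone for the levels were chosen only after results had been seen. Except where a reason is given, the cause was not tested.

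The number of genes that differ between Sst-positive and Sst-negative cells, 271, lay between 189 and 295 under the other alternatives, but not with the same genes throughout. Cluster 33 alone shared 119 genes with the 271, and 70 of the 271 had the opposite sign there, against 21 in cluster 11 alone, 27 in cluster 12 alone, 12 in cortical neighbourhoods and 38 with clusters 8, 16 and 18. It was 128 with no replicate block and 82 with clusters as blocks, all shared with the 271. With clusters as blocks 6 of the 271 had the opposite sign. Leaving out a section leaves 1 and allows no test. The filter on low counts removed no gene, so that leaving it off tests nothing. Of 1215 values of 58 named genes, 1107 kept direction and side of the threshold, 74 lost it, 20 gained it and 14 reversed. In cluster 11 alone Fosl2 had -0.038, Nr4a2 -0.55 and Ntn1 -0.36. In cluster 12 alone Nos1 had -0.076, Chodl -0.045, Tacr1 -0.17, Cxcl14 0.37, Nkx2-1 0.15 and Htr1d -0.50. In cluster 33 alone Pdzrn3 had 0.27, Nr2f1 0.38, Gad2 -0.57 and Adra1b 1.14. In cortical neighbourhoods only, Htr1d had -0.054.

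The Sst-positive share, 10.7% as the mean of both sections, was 9.94 to 11.5 with each section left out. It was 14.9 from 3 transcripts and 5.79 from 10, 9.68 at resolution 2, 4.31 thinned and 7.48 with clusters 8, 16 and 18. The limit acts by construction, and thinning also leaves out the cells under 100 transcripts. In deep-layer neighbourhoods the share of 11.6% was 17.9 from 3 transcripts, 4.999 from 10 and 13.98 with unnamed clusters competing, and 11.3 to 11.9 with each section left out. Around clusters 2 and 10 the 1.20% was 2.71 from 3 transcripts, 0.200 from 10 and 0.0965 thinned, and 0.916 to 1.49 with each section left out.

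The interneuron-like share moved at level 125 to 7.88 with 50 or more transcripts per cell, 8.59 at resolution 2 and 8.49 with each section clustered alone, and at level 133 to 7.83, 8.43 and 8.04, and to 7.13 at resolution 0.5. Over 16 class shares 55 of 80 values moved beyond counting error, and over 27 subtype marker shares 110 of 243 did.

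Cortical against striatal neighbourhoods gave 64 genes, 42 with Sst-positive from 10 transcripts and 48 to 85 otherwise. DESeq2, no filter and no block were not run there, and nothing was run for upper-layer neighbourhoods. The median absolute log2 ratio between levels, 0.28, was 0.27 from 3 transcripts, 0.29 from 10, 0.26 thinned, 0.55 per cubic micrometre and 0.26 in deep-layer neighbourhoods alone. At level 125, 136 genes and at level 133, 178 lay at or under the highest blank barcode.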

Other observations

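The overlap of Nos1 and Npy and the values by cluster below were chosen only after the results had been seen.

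Among Sst-positive interneuron-like cells, 148 of the 163 with Nos1 at level 125 and 168 of the 174 at level 133 also held Npy, each at 3 or more transcripts. This was 2.27 and 2.32 times the number that independence would give. The expected number pools the 3 interneuron-like clusters, of which cluster 33 was itself raised for both genes, and the overlap within a cluster was not counted. Pairs were counted at full depth, where cells with more transcripts reach both minimums more often. Other pairs also lay above independence in both sections, such as Cdh13 with Pdyn (1.93 and 2.48 times). Some lay below it, such as Npy with Rxfp1 (0.362 and 0.410 times).

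Clusters outside the interneuron-like name also held Sst-positive cells. Cluster 16, raised for Th, Pax6 and Gad2, held 11.2% of all Sst-positive cells at level 125 and 10.4% at level 133. Cluster 18, raised for Sema3e, Ramp3 and Npy, held 10.5% and 14.8%, and cluster 4, raised for Lhx8 and Nkx2-1, held 11.9% and 6.49%. In the neighbourhoods of the unnamed cluster 15, 167 of 812 (20.6%) and 70 of 389 interneuron-like cells were Sst-positive, around cluster 24 16.9% and 27.6%, and around cluster 26 20.7% and 23.3%, level 125 first.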
